A study of Mus musculus with 35 samples.

How the data were processed

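Bulk RNA-seq was measured in mouse thymocytes separated by flow sorting, per the labels. Double negative (DN) cells carry neither CD4 nor CD8 on their surface, and double positive (DP) cells carry both. The 35 libraries fall into 7 groups of 5. Young DN and young DP came from wild-type mice of 10 weeks, and aged DN and aged DP from wild-type mice of 60 weeks. WT DN and WT DP came from 10-week mice of the genotype Mettl3flox/wt; Cd4Cre, which carry 1 floxed allele, and KO DP from 10-week mice of the genotype Mettl3flox/flox; Cd4Cre. Cd4Cre is a transgene that deletes floxed sequence in cells that have switched on the Cd4 promoter. Knockout DN cells were not analysed here. The labels do not say whether the replicates of a group are separate animals or what a replicate number stands for, so the p-values measure the spread between these samples. They do not state whether the sort excluded cells of other lineages.

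The deposited table holds a whole-number read count per gene and library, not normalized. The submitters' processing notes name bcl2fastq, Trim Galore 0.4, STAR 2.5.1, Subread, HTSeq 2.0.3 and DESeq2, and the builds mm10 and GRCm39, without saying which step each served or which program made the counts. Per the labels' protocols, total RNA was made into libraries by standard BGI methods. Whether the counting used strand is not stated, so antisense and overlapping genes are uncertain, as are genes that share reads with near-identical copies, such as immunoglobulin and histocompatibility genes.

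The table has 41096 genes with identifiers of the C57BL/6NJ strain annotation. Of these, 13956 had no count in any library and 10414 carry an identifier in place of a name. A further 273 were named from the description in the table, 52 names were used for more than 1 gene, and 24 had been turned into dates. Names otherwise came from the table itself. Its positions are those of the strain assembly and none of the genes shared with the mm10 annotation had its start, so positions are given only as the table gives them. The table holds 0 genes of the mitochondrial chromosome and 0 of the Y chromosome, so no mitochondrial share was computed. The libraries hold 12391908 to 18820157 counts. A count of 0 over a group was given a floor of 3 counts over that group's total before TMM, which covers counting error only. Fold bounds set a TMM-scaled mean against this unscaled floor, so they are approximate.

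Groups were compared with edgeR 4.0.16 in R 4.3.3, using TMM normalization and quasi-likelihood tests on the libraries of the groups compared alone. Genes entered a test when they passed edgeR's filter on low counts (a minimum count of 10 and a minimum total of 15). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, with no fold threshold. The main comparisons were KO DP against WT DP, aged DP against young DP, aged DN against young DN, and young DP against young DN. Secondary comparisons were aged DP against aged DN, WT DP against WT DN, WT DP against young DP, WT DN against young DN, and the age by stage interaction, which tests whether the age effect differs between DP and DN cells. Comparisons against the young groups share the young libraries. Levels are CPM, the counts scaled to a common library total after TMM, given as mean ± SD with n = 5.

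Gene lists for cell types, pathways and library quality were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Each list needed at least 3 tested members, and p-values were adjusted over the lists of a comparison. Camera asks whether a list moved relative to the other genes. It was repeated with the correlation estimated per list, and with fry, which asks whether the members of a list moved on balance one way. Members called higher or lower were also counted after adjustment over the list alone. Principal components were computed on log2 CPM of the 500 most variable genes. Values per library were compared with exact 2-sided permutation tests over all 252 assignments.

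Mettl3 is named first. For each main comparison, the genes named next are the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM in at least 1 group, no overlap between the groups' values, and a real symbol. Immunoglobulin and T cell receptor segments, Xist, Y-linked genes, predicted genes, identifiers and date-like names were left out. Then come, from each list described, up to 2 members called higher and 2 called lower with the smallest adjusted p, or with none called the member with the smallest p. Where tested in a main comparison, Gpx4, Slc7a11, Acsl4, Tfrc, Fth1, Ftl1, Slc3a2, Aifm2, Hmox1 and Ptgs2 were named, as were Cd4, Cd8a, Cd8b1, Il2ra, Kit, Rag1, Rag2 and Ptcra. Some genes that this rule picks are not reported here. Ncoa4, Wtap and Ythdf2 are among list members not analysed here. Secondary comparisons name their 3 largest rises and falls. Genes named outside this rule are stated to be so.

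The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were RLE factors in place of TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, a fit over all 35 libraries, a replicate block, a 2-fold minimum, and leaving out each library in turn. Chosen after seeing the data were the removal of libraries that stand apart from their group (KO DP 2; aged DP 1 and 5; aged DN 1 and 5; young DN 5; WT DN 2; and WT DP 2 in the comparison with WT DN) and the Xist level as a covariate. Whether the replicate numbers pair DN with DP samples was checked by correlating libraries of the same number after removing the group means. In the aged groups all 5 pairs correlated (r from 0.13 to 0.29, across genes) and each DP library matched best with the DN library of its number. Among the splits of those aged libraries tested, 11 others part all 5 pairs, and none of these called a gene. The chain of steps was tested on simulated counts with known changes: at 2-fold it recovered 71.7% of changed genes for KO DP against WT DP, 81.6% for aged against young DP, 34% for aged against young DN, and 74.4% for young DP against DN. At 1.5-fold these shares were 14%, 59.2%, 4% and 44%. Calls on unchanged genes numbered 8, 15, 2 and 5 in the same order of comparisons. The simulated genes varied independently and no simulated library was made to stand apart, unlike in the data.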

Results

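Thymocytes of the DN and DP stages were profiled in young, aged, heterozygous and knockout mice, with 5 libraries in each of 7 groups. Total counts per library ran from 12391908 (KO DP 2) to 18820157 (WT DN 3). Group means in megacounts (M) were 14.8 M in young DN, 14.9 in young DP, 14.2 in aged DN, 14.7 in aged DP, 17 in WT DN, 13.9 in WT DP and 14.2 in KO DP. WT DN libraries were deeper than young DN libraries (exact permutation p = 0.00794, the smallest that 252 assignments allow, adjusted p = 0.0289 over 40 such tests), yet fewer genes had a count in them, 17000 ± 778 against 19400 ± 261 (the same p-values). The first principal component parted DN from DP libraries and carried 73.3% of the variance among the 500 most variable genes, and the second carried 8.35%. Several libraries stood apart from their group. Aged DN 5 and WT DN 2 were high in the B cell and dendritic cell marker lists, with B cell markers averaging 1090 CPM and 410 CPM, against 95.7 and 64.1 CPM in the next library of each group. In aged DP 5 they averaged 139 CPM. Aged DN 1 carried the markers of gamma delta and innate-like T cells, and KO DP 2 had the lowest Rag1 of its group (1930 CPM). In KO DP 2 only 12306 genes had a count, against 16042 to 19656 in the other KO DP libraries. Xist, which is transcribed from the inactive X chromosome of females, was high in all young and aged libraries but varied within the WT and KO groups, at 2400 CPM in KO DP 1 and 1.08 CPM in KO DP 3.

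**Figure D1:**
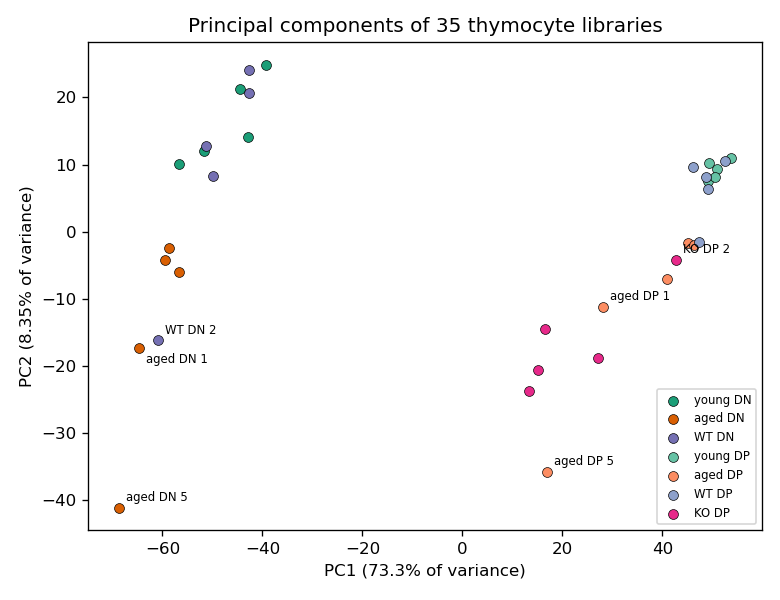
Principal components of log2 CPM over the 500 most variable genes, with component 1 (73.3% of the variance) on the x axis and component 2 (8.35%) on the y axis; each point is a library, coloured by group. DN and DP libraries part along component 1, and the labelled libraries lie away from their groups.

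The comparison of KO DP with WT DP asks what loss of Mettl3 changes in DP thymocytes. Libraries labelled KO carried more RNA of marker genes of B cells, antigen-presenting cells, granulocytes and NK cells than WT DP libraries. Cd22 and Pax5 belong to the B lineage, Cd74 and H2-Eb1 to class II antigen presentation, S100a9 to neutrophils and Gzmb to cytotoxic cells. None of these marker lists kept its call with an estimated correlation, and the counts do not show which cells the RNA came from. Some genes of maturing thymocytes, such as H2-K1 and Gimap3, and some interferon-induced genes, such as Irf7, were higher too. Fewer genes fell than rose, and the core ferroptosis genes, Gpx4 and Slc7a11 among them, were not called. Mettl3 itself encodes the catalytic subunit of the complex that writes N6-methyladenosine on RNA, and its gene-level count was not lower in the libraries labelled KO.

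Mettl3 (MGP_C57BL6NJ_G0021696, chromosome 14, 48389682 to 48400187, minus strand, exons not resolved) stood at 51.7 ± 5.13 CPM in KO DP and 50.8 ± 3.85 CPM in WT DP (log2 0.05, adjusted p = 0.862). Values ran from 47.8 to 60.6 CPM and from 44.5 to 54.1 CPM. A gene-level count keeps reads from outside the deleted part, which the labels do not name, so it does not test the deletion. Of 13233 genes tested, 211 were called, 196 higher and 15 lower in KO DP, and 158 of them changed at least 2-fold; 1924 had an unadjusted p under 0.05. The count depended on single libraries. It was 534 without KO DP 2 (451 higher and 83 lower), 118 without KO DP 1, 127 without KO DP 4, 135 without WT DP 1, 117 without WT DP 3, 138 without WT DP 4 and 101 without WT DP 5. The fit over all 35 libraries called 181, of which 83 are among the 211, and a replicate block 61. DESeq2 called 606, 504 higher and 102 lower.

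The largest rise with no overlap between the groups was in Serpina3g, a serine protease inhibitor, from 0.205 ± 0.134 to 12.2 ± 5.42 CPM (log2 5.87, SE 0.47, adjusted p = 7.79e-05). The B cell gene Cd22 rose from 0.855 ± 1.14 to 28 ± 17.1 CPM (log2 5.01, adjusted p = 0.00409). Among the other largest rises were the protease inhibitor Slpi (log2 5.71), the complement component C3 (5.32), the costimulatory ligand Icosl (4.33), the B lineage factor Pax5 (4.24) and the IgM receptor Fcmr (4.2). The calls on Cd22, Pax5 and Fcmr ended in the fit over all 35 libraries, and those on Cd22, Pax5, Slpi and C3 with a replicate block. The largest falls were smaller. The metalloprotease Adam12 fell from 82 ± 16.5 to 39.7 ± 8.81 CPM (log2 -1.03, adjusted p = 0.0117), a call that held without any 1 library but ended in the fit over all 35 libraries and with a replicate block. Fnbp1l (-1.5), Sbf2 (-1.2), Atrnl1 (-1.02), Il17re (-0.93), Ssx2ip (-0.87), Sort1 (-0.81) and Lonrf1 (-0.75) also fell. Each of these 7 calls ended without at least 5 of the 10 libraries in turn. Their highest adjusted p-values ranged from 0.0587 for Lonrf1 without WT DP 5 to 0.129 for Il17re without WT DP 1.

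Markers of other blood cells moved up together, and the list test called them all with the preset correlation and none with an estimated correlation. Of 18 B cell genes, 15 were called higher (17 adjusted over the list alone, median log2 3.49, camera adjusted p = 1.46e-27, and 0.0586 with an estimated correlation). The immunoglobulin light chain gene Igkc rose from 12.5 ± 3.94 to 143 ± 39.9 CPM (adjusted p = 1.63e-05) and the B cell receptor gene Cd79a by 3.76 on the log2 scale. Of 12 dendritic cell genes, 7 were higher (8 adjusted over the list alone, median 2.22, camera adjusted p = 1.78e-11, and 0.0678 with an estimated correlation), among them H2-Eb1 (6.03 to 58.8 CPM) and Cd74 (19.7 ± 9.76 to 200 ± 71.4 CPM). Granulocyte genes (3 of 5, 5 adjusted over the list alone, median 3.22, adjusted p = 3.16e-08, and 0.0792 with an estimated correlation) included S100a9 (log2 3.74) and Ngp (2.83). NK and innate lymphoid genes (3 of 8, 6 adjusted over the list alone, median 1.82, adjusted p = 8.99e-08, and 0.0586 with an estimated correlation) included Gzmb (4.76) and Eomes (4.48). Macrophage genes (4 of 10, 6 adjusted over the list alone, median 1.41, adjusted p = 5.42e-06, and 0.0792 with an estimated correlation) included Csf1r (3.21) and C1qa (3.16). Plasma cell genes (3 of 8, 4 adjusted over the list alone, median 1.61, adjusted p = 0.00682, and 0.344 with an estimated correlation) included Jchain (1.98) and Ighg2c (3.97). The calls on C1qa, Ngp and Ighg2c ended without some libraries, with the highest adjusted p at 0.0562 for C1qa without WT DP 5, 0.0551 for Ngp without WT DP 3 and 0.0643 for Ighg2c without WT DP 4. In the fit over all 35 libraries the calls on Cd79a, Jchain, H2-Eb1, Cd74 and C1qa ended, and with a replicate block those on Ngp, Ighg2c, Eomes, Csf1r and C1qa.

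Some genes of stages before and after DP also rose. The class I gene H2-K1 went from 80.6 ± 9.23 to 320 ± 120 CPM (adjusted p = 0.00052) and the GTPase Gimap3 from 12.9 ± 1.4 to 42.7 ± 11.8 CPM (0.000306). The selection and single positive list had 6 of 21 members higher (13 adjusted over the list alone, median 0.65, camera adjusted p = 6.29e-11, and 0.0678 with an estimated correlation). Among DN stage genes 4 of 17 were higher (10 adjusted over the list alone, median 1, adjusted p = 3.25e-05, and 0.0678 with an estimated correlation). They included Lmo2 (log2 3.82), the Notch target Dtx1 (17.8 ± 4.22 to 67.1 ± 26.4 CPM) and the interleukin-2 receptor gene Il2ra (12.7 ± 3.03 to 43.5 ± 23.6 CPM, adjusted p = 0.0288, and up to 0.0921, without WT DP 3). Gamma delta and innate-like T cell genes (3 of 10, 4 adjusted over the list alone, median 1.01, adjusted p = 1.84e-05, and 0.0832 with an estimated correlation) included Ccl5 (3.67) and Blk (2.48). Of 28 interferon-response genes 4 were called higher, 16 adjusted over the list alone (median 0.93, adjusted p = 1.78e-11, and 0.219 with an estimated correlation), with Irf7 at 28.6 ± 8.63 against 10.1 ± 3.07 CPM and Ifi203 at 55.7 against 27.9 CPM. Bmf (log2 0.96) and Bcl2 (1.06), which act for and against apoptosis, both rose, as did the cytokine signalling inhibitor Cish (2.33). Without WT DP 5 the adjusted p of Bcl2 was 0.0598. In the fit over all 35 libraries the calls on Lmo2, Blk and Ifi203 ended, and with a replicate block those on Lmo2, Il2ra, Ccl5, Bmf, Bcl2 and Cish.

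DP stage genes were not called as a list (median -0.17, camera adjusted p = 0.254). Rag1 stood at 3920 ± 1280 CPM in KO DP and 6240 ± 888 CPM in WT DP (log2 -0.65, adjusted p = 0.177), and Rag2 at 248 and 319 CPM (adjusted p = 0.12). Cd4 (1660 and 1900 CPM), Cd8a (2150 and 2470 CPM), Cd8b1 (adjusted p = 0.96), Ptcra (0.121) and Kit (0.452) were not called either. Cell cycle lists moved down with no member called over all genes: S phase (4 of 30 lower adjusted over the list alone, median -0.33, adjusted p = 7.8e-06, and 0.495 with an estimated correlation) and G2/M (median -0.28, adjusted p = 5.76e-06, and 0.481 with an estimated correlation). The lists of m6A writers (median -0.23, adjusted p = 0.012, and 0.0832 with an estimated correlation, 1 lower adjusted over the list alone) and of m6A erasers and readers (median -0.25, adjusted p = 0.00829, and 0.283 with an estimated correlation) moved down likewise, with Rbm15 at log2 -0.49 (adjusted p = 0.106) and Alkbh5 at -0.41 (0.157). Higher lists with small medians were negative selection signals (median 0.32, adjusted p = 0.0192, and 0.321 with an estimated correlation), ribosomal protein genes (0.2, adjusted p = 0.00106, and 0.71 with an estimated correlation) and cytokine signalling inhibitors (0.11, adjusted p = 0.0482, and 0.321 with an estimated correlation). Without KO DP 2, which stands apart, the calls on ribosomal protein genes (0.455) and cytokine signalling inhibitors (0.0909) ended.

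Ferroptosis is a form of cell death driven by iron-dependent lipid peroxidation; Gpx4 and Slc7a11 restrain it and Acsl4 promotes it. None of the 3 ferroptosis lists was called. Suppressors had a median of -0.01 and a mean of 0.18 over 25 genes (camera adjusted p = 0.746, direction up), drivers -0.01 and 0.15 over 22 genes (0.861, up), and iron handling genes -0.02 and 0.04 over 20 genes (0.746, down). The called members were Scd1, a lipid desaturase among the suppressors, from 1.35 ± 1.06 to 24.3 ± 22.7 CPM (adjusted p = 0.0464, lost without 9 of the 10 libraries in turn and 0.161 without WT DP 5), and the NADPH oxidase gene Cybb among the drivers, from 1.37 ± 0.601 to 15.7 ± 11 CPM (0.00299). Gpx4 was at 99.1 ± 47.9 and 77.5 ± 11.8 CPM (adjusted p = 0.5), Slc7a11 at 186 ± 46.9 and 255 ± 60.8 CPM (0.325), Ftl1 at 113 and 78.2 CPM (0.241) and Fth1 at 330 ± 66.4 and 334 ± 56.9 CPM (0.981). Tfrc (adjusted p = 0.956), Acsl4 (0.863), Slc3a2 (0.462) and Hmox1 (0.775) were not called.

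**Figure D2:**
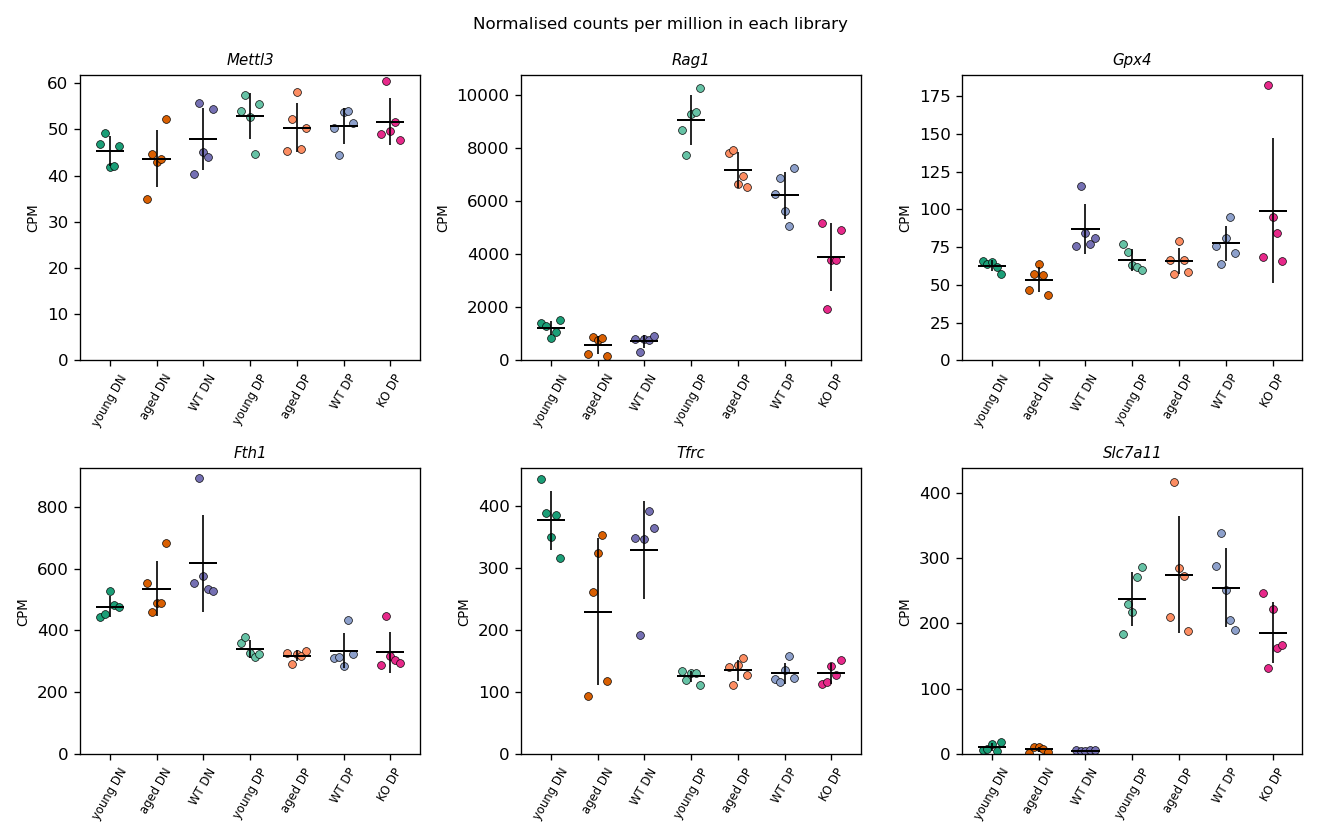
CPM of Mettl3, Rag1, Gpx4, Fth1, Tfrc and Slc7a11 in each of the 35 libraries by group; each point is a library, the bar is the mean and the line ± SD, n = 5. Mettl3 lies at 51.7 CPM in KO DP and 50.8 CPM in WT DP, and Slc7a11 at 238 CPM in young DP against 10.6 CPM in young DN.

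Aged DP thymocytes were compared with young DP thymocytes to ask what changes as the thymus involutes with age. B cell and plasma cell genes, such as Igkc, Jchain and Igha, were higher with age, and so were class II genes such as Cd74. None of their lists kept its call with an estimated correlation. Bmpr1a, a receptor for bone morphogenetic proteins, rose from near absence. The RNA-binding protein gene Igf2bp3, best known from fetal and tumour cells, fell, as did the Wnt receptor Fzd10 and the citrullinating enzyme Padi4. Rag1 and Ets2, which DP cells express strongly, were somewhat lower.

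Of 13059 genes tested, 123 were called, 81 higher and 42 lower in aged DP; 65 changed at least 2-fold and 1538 had an unadjusted p under 0.05. The count was 73 without young DP 2, 64 without young DP 3, 58 without young DP 4 and 62 without young DP 5. Mettl3 was at 50.3 ± 5.31 CPM in aged and 52.9 ± 4.97 CPM in young DP (log2 -0.05, adjusted p = 0.889). Bmpr1a rose from 0.471 ± 0.191 to 16 ± 3.61 CPM (log2 5.1, SE 0.27, adjusted p = 3.52e-08). The other largest rises, most of them in B cell or antigen-presentation genes, had a wide spread among the aged libraries. Cd22 had a mean of 22 ± 43.4 CPM against 0.137 (log2 7.27, adjusted p = 0.0247), with 99.6 CPM in aged DP 5. Siglecg (5.71), Ms4a1 (5.71), Scd1 (4.72), Blk (4.37) and Ctsh (4.23) followed. Without young DP 4 the adjusted p was 0.093 for Cd22, 0.106 for Siglecg, 0.0857 for Ms4a1, 0.136 for Scd1 and 0.0961 for Ctsh, while Blk kept its call without any 1 library (highest 0.0382) but lost it without both aged DP 1 and aged DP 5, which stand apart. The calls on Cd22, Siglecg, Ms4a1, Scd1 and Ctsh ended in the fit over all 35 libraries, and those on Siglecg, Scd1 and Ctsh without aged DP 1 and aged DP 5.

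Falls were tighter. Igf2bp3 fell from 26.8 ± 2.34 to 4.36 ± 1.82 CPM (log2 -2.6, adjusted p = 2.47e-06), the kinase gene Cdc42bpa from 19.1 ± 2.27 to 3.92 ± 1.66 CPM (-2.27, 5.61e-05) and the lipid flippase gene Atp9a from 16.2 ± 1.53 to 4.24 ± 0.251 CPM (-1.92, 1.21e-06). Fzd10 (-2.47), Rtkn (-2.35), Wscd1 (-2.34), the matrix proteoglycan gene Hspg2 (-1.95) and Padi4 (-1.5) fell as well, and all 8 falls held without any 1 library. In the fit over all 35 libraries the calls on Fzd10, Wscd1 and Hspg2 ended. Most of these genes were also lower in WT DP, of the same 10 weeks as young DP. WT DP means were 4.03 CPM for Igf2bp3, 5.95 for Cdc42bpa, 7.99 for Atp9a, 3.93 for Fzd10 (9.3 in young DP), 1.96 for Rtkn (5.61), 5.04 for Wscd1 (11) and 15.5 for Hspg2 (47.7). Padi4 was at 19.9 CPM in WT DP, 24.2 in young DP and 8.41 in aged DP, and Bmpr1a at 0.405 CPM in WT DP. Rag1 fell from 9070 ± 933 to 7180 ± 662 CPM (-0.32, 0.0495), Ets2 from 1170 ± 43.8 to 941 ± 63.9 CPM (-0.29, 0.0181) and Kit from 6.39 to 2.75 CPM (-1.19, 0.0303). The calls on Rag1 and Kit ended without 7 and 8 of the 10 libraries in turn (up to 0.128 and 0.0946, without young DP 4), and that on Ets2 without 3 (up to 0.0573, without young DP 5). The calls on Rag1 and Ets2 also ended without both libraries that stand apart, those on all 3 genes in the fit over all 35 libraries, and that on Rag1 with a replicate block. WT DP, of 10 weeks, was at 6240 CPM for Rag1, below aged DP, at 966 CPM for Ets2 and at 3.52 CPM for Kit. Cd4 (adjusted p = 0.95), Cd8a (0.23), Cd8b1 (0.561), Rag2 (0.143), Ptcra (0.884) and Il2ra (0.774) were not called.

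Among lists, B cell genes were higher (5 of 14, 13 adjusted over the list alone, median 3.03, camera adjusted p = 4.5e-10, and 0.387 with an estimated correlation), with Igkc from 6.69 ± 2.38 to 163 ± 128 CPM. Plasma cell genes followed (4 of 9, 7 adjusted over the list alone, median 1.94, adjusted p = 5.44e-08, and 0.315 with an estimated correlation), with Jchain (3.82) and Igha (2.93), as did dendritic cell genes (5 of 12, 9 adjusted over the list alone, median 2.44, adjusted p = 1.03e-07, and 0.315 with an estimated correlation), with H2-Ab1 (2.9) and Cd74 (3.7). Of 28 interferon-response genes none was called over all genes and 14 were higher adjusted over the list alone (median 0.62, adjusted p = 5.44e-08, and 0.454 with an estimated correlation). Macrophage genes (median 0.51, with Mpeg1 at 2.45, adjusted p = 0.0348, and 0.454 with an estimated correlation) and selection and single positive genes (median 0.24, with Cd2 at 0.35, adjusted p = 0.0155, and 0.622 with an estimated correlation) were higher by less. Both calls ended without aged DP 1 and aged DP 5, which stand apart (adjusted p = 0.142 for macrophage and 0.96 for selection and single positive genes). Aged DP 5 had the latter at a mean of 106 CPM, against 60.6 to 70.9 CPM in the other aged DP libraries. Without young DP 4 the adjusted p of H2-Ab1 was 0.0682, and those of Cd74 and Mpeg1 were 0.093. The call on Cd2 (0.0407) ended without 7 of the 10 libraries in turn (up to 0.11, without young DP 4). Those on Cd2 and Mpeg1 also ended without aged DP 1 and aged DP 5, and those on Cd2, Mpeg1, Igha, H2-Ab1 and Cd74 in the fit over all 35 libraries. Small upward shifts were also called for G2/M (median 0.17, adjusted p = 2.32e-06, and 0.589 with an estimated correlation), S phase (0.14, adjusted p = 0.000804, and 0.622 with an estimated correlation), cholesterol synthesis (0.2, adjusted p = 0.00264, and 0.574 with an estimated correlation) and glycolysis (0.09, adjusted p = 0.0141, and 0.454 with an estimated correlation). Among their members, the mitochondrial kinase gene Pdk1 rose from 296 ± 16.1 to 394 ± 26.4 CPM (adjusted p = 0.00149). Outside these lists, the cell cycle inhibitor gene Cdkn2c rose from 114 ± 24.6 to 166 ± 9.96 CPM (0.0291, and 0.0959 without young DP 4). Both calls ended in the fit over all 35 libraries, and that on Cdkn2c without aged DP 1 and aged DP 5. DP stage genes (2 of 19 lower, 5 adjusted over the list alone, median -0.08, adjusted p = 0.0069, and 0.454 with an estimated correlation) and m6A erasers and readers (median -0.11, adjusted p = 0.00282, and 0.315 with an estimated correlation) moved down, Igf2bp3 being the called member of the latter. Small downward shifts were called for p53 targets (median -0.08, adjusted p = 0.038, and 0.454 with an estimated correlation), T cell receptor signalling (-0.06, adjusted p = 0.0279, and 0.454 with an estimated correlation) and the Wnt and Tcf list (-0.07, adjusted p = 0.0155, and 0.454 with an estimated correlation). Without the same 2 libraries the calls on DP stage (0.0549), glycolysis (0.0741) and T cell receptor signalling genes (0.0559) ended. DP stage genes averaged 1580 ± 67.1 CPM in young DP, 1400 ± 79.1 in aged DP and 1370 ± 66.7 in WT DP, of 10 weeks. Age alone thus does not order the means of this list, though it was not called between WT DP and young DP.

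The ferroptosis drivers were called slightly higher (median 0.11 over 21 genes, 1 called, Cybb, camera adjusted p = 0.0263, and 0.315 with an estimated correlation). The call ended without aged DP 4 (0.0614), young DP 1 (0.0511) or young DP 5 (0.0588). Suppressors (adjusted p = 0.233) and iron handling genes (0.29) were not called. Cybb was at 9.67 ± 14.4 CPM in aged and 0.911 CPM in young DP (adjusted p = 0.0437, and 0.122 without young DP 4). Gpx4 was at 65.6 and 66.8 CPM (adjusted p = 0.993), Slc7a11 at 275 ± 89 and 238 ± 41.2 CPM (0.666), Acsl4 at 89.7 and 77.9 CPM (0.254) and Hmox1 at 1.71 and 0.98 CPM (0.404). Tfrc (adjusted p = 0.617), Fth1 (0.763), Ftl1 (0.837) and Slc3a2 (0.831) were not called.

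The changes in libraries labelled KO and those with age, which share no library, overlapped in genes of B cells and class II presentation. Of 12824 genes tested in both, 29 were called in the same direction, 27 higher (0.973 by chance) and 2 lower (0.048 by chance), and 0 in opposite directions (0.603 by chance). Opposite calls numbered 2 by DESeq2 (4.48 by chance), 3 without the libraries that stand apart (1.25), 2 without KO DP 2 (1.64) and 1 without KO DP 5 (0.599). The shared genes include Cd22, Ms4a1, Igkc, Jchain, Pou2af1, Blk, Cd74, H2-Aa, H2-Ab1, Cybb and Scd1. They also include Irf1, a transcription factor of the interferon response (log2 0.97 in KO DP and 0.71 in aged DP), Il12rb1 (0.7 and 0.5) and Cd82 (0.6 and 0.55), and the lower pair Adam12 (-1.03 and -0.91) and Atrnl1 (-1.02 and -0.48). Across genes, which are not independent replicates, the log2 changes correlated with r = 0.45 and rho = 0.18, and r was 0.28 without aged DP 5. The shared count was 41 without KO DP 2, 19 without KO DP 1, KO DP 4, WT DP 3 or WT DP 5, 12 without young DP 1 or young DP 2, 10 without young DP 3 or young DP 5, and 9 without young DP 4.

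**Figure D3:**
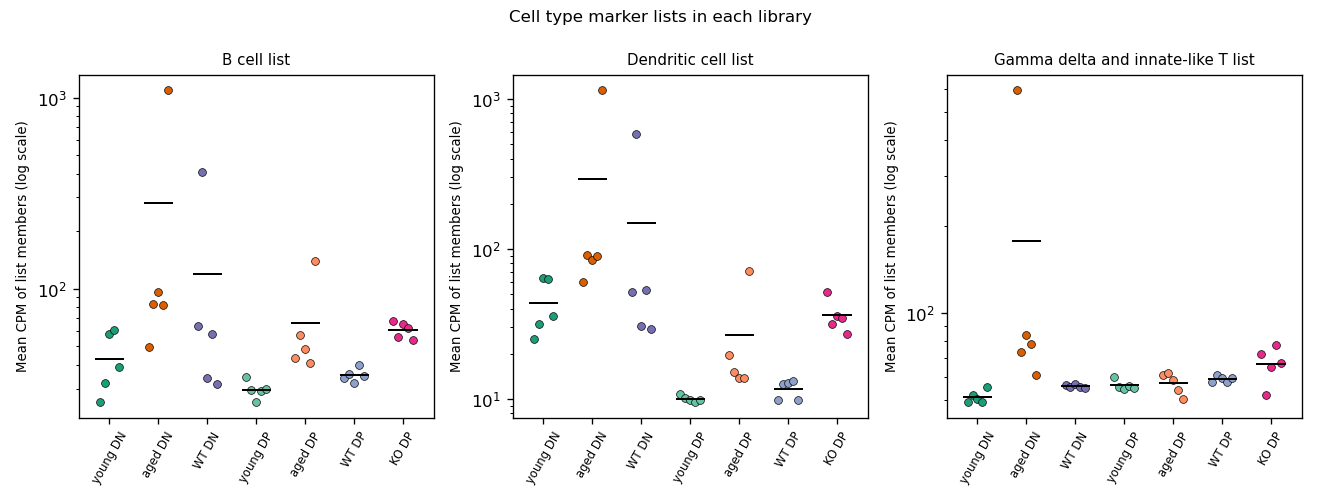
Mean CPM (log axis) of the B cell, dendritic cell and gamma delta or innate-like T cell lists in each library by group; each point is a library and the bar is the group mean. B cell markers averaged 60.9 CPM in KO DP against 35.4 in WT DP, and 65.7 CPM in aged DP against 29.7 in young DP.

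Aged DN thymocytes were compared with young DN thymocytes for the same question at the earlier stage. Some receptors of innate-like and NK-like lymphocytes, Cxcr6, Cxcr3, Klra7, Klre1 and Klrk1, were higher with age, while Klra5, of the same family as Klra7, was lower. The neutrophil-associated genes Itgb2l and Chil1 and the myeloid gene Slfn4 were lower. The calls on Itgb2l, Chil1, Slfn4, Klra5, Cxcr6 and Klre1 each ended without 7 to 9 of the 10 libraries in turn. That on Klra7 ended without 5 and that on Cxcr3 without 4, while Klrk1 kept its call without any 1 library. Bmpr1a rose and Igf2bp3 fell here too. The iron exporter gene Slc40a1 was lower.

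Of 13873 genes tested, 37 were called, 22 higher and 15 lower in aged DN, 36 of them by at least 2-fold, while 3049 had an unadjusted p under 0.05. DESeq2 called 924 genes, 700 higher and 224 lower. With edgeR the count was 2193 in the fit over all 35 libraries, 1 with a replicate block, and 706 (562 higher, 144 lower) without aged DN 1, aged DN 5 and young DN 5, which stand apart. Leaving out 1 library moved the count to 185 without aged DN 1, 56 without aged DN 5, 14 without aged DN 3 and 17 without aged DN 4 or young DN 4. It was 12 without young DN 1, 13 without young DN 3, and 10 without young DN 2 or young DN 5. Mettl3 was at 43.7 ± 6.16 CPM in aged and 45.3 ± 3.2 CPM in young DN (log2 -0.02, adjusted p = 0.935). Igf2bp3 fell from 30.8 ± 1.59 to 3.1 ± 0.289 CPM (log2 -3.28, SE 0.12, adjusted p = 6.17e-07). Bmpr1a rose from 0.754 ± 0.336 to 17.1 ± 12.5 CPM (4.52, 0.00916) and the tight junction gene Tjp1 from 0.735 to 7.15 CPM (3.3, 0.00868). Prss12 (4.34), Cxcr6 (3.13), the potassium channel gene Kcnj8 (2.69), Klra7 (2.44), F2rl1 (2.3) and Fam46c (2.14) rose too, and Klrk1 went from 14.4 ± 2.34 to 48.4 ± 11.4 CPM (adjusted p = 0.00785). Slfn4 fell from 66.2 ± 48.7 to 2.6 ± 2.9 CPM (-4.64, 0.0492). Itgb2l (-3.44), Tmc5 (-3.11), Chil1 (-2.96), Klra5 (-2.19), Mmp17 (-1.54) and Nat8l (-1.36) fell as well. In WT DN, also of 10 weeks, Igf2bp3 (2.78 CPM), Tmc5 (1.08) and Kcnj8 (5.27) stood near their aged DN levels, and Bmpr1a (1.19) and Prss12 (0.657) near those of young DN. Only Igf2bp3, Tjp1, Tmc5 and Klrk1 of the named genes kept their calls without any 1 library, and of these only Igf2bp3 kept it with a replicate block. The highest adjusted p-values of the others ran from 0.0539 for Bmpr1a, Prss12 and Kcnj8 without young DN 5 to 0.17 for Cxcr6 and Klre1 without young DN 2.

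Gamma delta and innate-like T cell genes were higher as a list (3 of 17, 12 adjusted over the list alone, median 2, camera adjusted p = 3.49e-07, and 0.351 with an estimated correlation). B cell genes (0 of 19 called, 19 adjusted over the list alone, median 3.27, adjusted p = 3.46e-07, and 0.582 with an estimated correlation) and plasma cell genes (0 of 9, 7 adjusted over the list alone, 2.45, adjusted p = 8.27e-06, and 0.341 with an estimated correlation) were higher with a wide spread. Igkc was at 497 ± 649 CPM in aged and 47.1 ± 28.2 CPM in young DN (adjusted p = 0.12). Higher too were dendritic cell genes (median 1.71, adjusted p = 0.00591, and 0.582 with an estimated correlation), NK and innate lymphoid genes (1 of 11 called, 6 adjusted over the list alone, 0.9, adjusted p = 0.00396, and 0.561 with an estimated correlation), interferon-response genes (1.08, adjusted p = 6.3e-07, and 0.582 with an estimated correlation) and selection and single positive genes (1.32, adjusted p = 0.000272, and 0.503 with an estimated correlation). Granulocyte genes were lower (0 of 11, 9 adjusted over the list alone, median -3.26, adjusted p = 2.74e-09, and 0.351 with an estimated correlation), with lactoferrin, Ltf, at 7.88 ± 6.15 and 133 ± 86.7 CPM (adjusted p = 0.0528). Lists of dividing and growing cells were lower with no member called over all genes: S phase (median -0.54, camera adjusted p = 2.96e-07), G2/M (-0.53, 8.36e-07), ribosome biogenesis (-0.37, 5.49e-07), oxidative phosphorylation (-0.22, 3.9e-05), DP stage (-0.59, 0.000568), RNA processing (-0.19, 0.0058) and V(D)J recombination (-0.24, 0.0186), each with an adjusted p = 0.582 with an estimated correlation. Without aged DN 1, aged DN 5 and young DN 5 the calls on DP stage (0.423), G2/M (0.0827), RNA processing (0.0738) and V(D)J recombination genes (0.0967) ended.

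In the same comparison the ferroptosis suppressors (median -0.08, mean 0.04, camera adjusted p = 0.606), drivers (0.536) and iron handling genes (0.339) were not called. Slc40a1 fell from 4.92 to 0.504 CPM (log2 -3.24, adjusted p = 0.0317, and 0.0922 without young DN 4). Gpx4 was at 53.5 and 62.8 CPM (adjusted p = 0.268), Tfrc at 230 ± 118 and 376 ± 47.3 CPM (0.244), Fth1 at 534 and 476 CPM (0.334) and Slc7a11 at 7.08 and 10.6 CPM (0.501). Acsl4 (adjusted p = 0.614), Ftl1 (0.411), Slc3a2 (0.357), Aifm2 (0.293), Hmox1 (0.672) and Ptgs2 (0.338) were not called. The DN markers Il2ra (394 ± 202 and 652 ± 55 CPM, adjusted p = 0.247) and Kit (0.227), and Rag1 (582 ± 346 and 1230 ± 278 CPM, 0.199), Rag2 (0.237), Ptcra (0.274), Cd4 (0.211), Cd8a (0.188) and Cd8b1 (0.207) were not called.

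Young DP and young DN cells were compared to set the age and genotype changes beside those of normal development. DP cells carried the coreceptor genes Cd4, Cd8a and Cd8b1, the recombinase genes Rag1 and Rag2, and Bcl2l1, which sustains DP survival. DN cells carried Il2ra, Kit, the Notch target Hes1 and Myc with its ribosome biogenesis targets. The DN libraries also held RNA of marker genes of gamma delta T cells, NK cells, B cells and granulocytes. The cystine transporter gene Slc7a11 was far higher in DP cells, and the transferrin receptor gene Tfrc in DN cells.

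Of 13772 genes tested, 9697 were called, 4671 higher and 5026 lower in DP, 3923 of them by at least 2-fold. Cd4 rose from 29.4 ± 43.8 to 1840 ± 71.4 CPM (log2 5.97, adjusted p = 1.76e-06) and Cd8a from 49.8 ± 61.2 to 2660 ± 140 CPM (5.74, 3.8e-07), where young DN 5 alone carried Cd4 at 107 CPM. The other largest rises were Fn3k (5.65), the amino acid transporter gene Slc6a19 (5.37), Xrra1 (5.26), Adcy1 (5.15), Tdrp (4.81) and the corepressor gene Tle2 (4.8). Rag1 rose from 1230 ± 278 to 9070 ± 933 CPM (2.9, 1.36e-10), Ets2 from 123 to 1170 CPM (3.25, 2.46e-13) and Bcl2l1 from 38.9 to 309 CPM (2.99, 4.71e-11). Rag2 (2.34), Cd8b1 (4.65), Bcl6 (3.66), Cd5 (2.46), Themis (1.77), Egr1 (1.84) and the death receptor gene Fas (4.27) were higher as well. Mettl3 was slightly higher in DP (log2 0.23, adjusted p = 0.0158), Mettl14 too (0.2), while Mettl16 was lower (-1.09). In the fit over all 35 libraries Mettl3 and Mettl14 were not called.

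Among the largest falls from DN to DP were neutrophil genes with no DP counts: Cxcr2 (at least about 233-fold lower), Retnlg (at least about 219-fold), Ifitm6 (at least about 157-fold) and Chil1 (at least about 139-fold). The lipoxygenase gene Alox5 (at least about 126-fold) also had no DP counts. Lcn2, Mmp8 and Esm1, at 36.1, 19.8 and 13.7 CPM in DN, were nearly absent from DP, at 0.0273, 0.0137 and 0.0137 CPM. Il2ra fell from 652 ± 55 to 14.3 ± 5.14 CPM (log2 -5.5, adjusted p = 4.98e-12), Hes1 from 62.8 to 0.504 CPM (-6.96, 1.28e-12), Kit from 81.9 to 6.39 CPM (-3.67) and Myc from 291 to 25.4 CPM (-3.51, 1.69e-13). Il7r (-4.37), Bcl2 (-2.12), Ptcra (-1.39), Cdkn1a (-4.06), the gamma delta genes Tcrg-C4 (-6.88) and Cd163l1 (-7.55), Cd74 (-4.47) and Gzma (-3.14) fell as well.

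DP stage genes (18 of 19 higher, median 2.52, camera adjusted p = 4.56e-08, and 0.34 with an estimated correlation) and T cell receptor signalling genes (19 of 24 higher, 3 lower, 0.86, adjusted p = 1.9e-06, and 0.254 with an estimated correlation) were higher in DP. DN stage genes were lower (19 of 20, median -3.62, adjusted p = 1.17e-06, and 0.0396 with an estimated correlation, the only list of this comparison to keep its call). Ribosome biogenesis (25 of 26 lower, -1.85, adjusted p = 3.21e-11, and 0.159 with an estimated correlation) included Srm (-3.42). Ribosomal protein genes (45 of 47, median -0.92, camera adjusted p = 4.36e-09), S phase (29 of 30, -0.96, 1.15e-07), B cell (18 of 19, -4.07, 7.42e-05), dendritic cell (12 of 15, -2.86, 0.0006) and cholesterol synthesis genes (17 of 21, -0.79, 0.00112) were lower, each with an adjusted p = 0.5 with an estimated correlation. Gamma delta (15 of 16, -5.04, adjusted p = 5.96e-06, and 0.195 with an estimated correlation), NK (9 of 10, -5.05, adjusted p = 0.000429, and 0.254 with an estimated correlation), granulocyte (11 of 11, adjusted p = 1.06e-05, and 0.371 with an estimated correlation), oxidative phosphorylation (24 of 37, -0.33, adjusted p = 0.00148, and 0.542 with an estimated correlation) and interferon-response genes (22 of 29, -1.34, adjusted p = 0.0123, and 0.599 with an estimated correlation) were lower too. Adjusted over the list alone, 14 dendritic cell and 18 cholesterol synthesis genes were lower. G2/M genes (14 of 30 higher, 6 adjusted over the list alone, camera adjusted p = 0.142), V(D)J recombination (0.0888), apoptosis regulators (0.393) and p53 targets (0.338) were not called.

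Between the stages, the ferroptosis drivers were lower in DP (5 of 25 higher, 17 lower, 18 lower adjusted over the list alone, camera adjusted p = 0.0348, and 0.404 with an estimated correlation). Suppressors (6 of 27 higher, 16 lower, adjusted p = 0.0626) and iron handling genes (4 of 21 higher, 12 lower, 0.0867) were not called. Slc7a11 rose from 10.6 ± 6.29 to 238 ± 41.2 CPM (log2 4.48, adjusted p = 3.55e-09). Tfrc fell from 376 ± 47.3 to 125 ± 8.89 CPM (-1.58, 2.87e-10), the iron reductase gene Steap3 from 24 to 0.79 CPM (-4.91), Fth1 from 476 to 340 CPM (-0.48, 2.43e-05), and Slc3a2 (-0.51) and Aifm2 (-4.12) fell as well. Ptgs2, at 5.97 ± 5.08 CPM in DN, was at 0.0142 CPM in DP (-8.06, 1.56e-06). Ftl1 rose from 46.5 to 73.2 CPM (0.66, 0.000567). Gpx4 (66.8 and 62.8 CPM, adjusted p = 0.299), Acsl4 (0.0783) and Hmox1 (0.0591) were not called.

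The same stages differed likewise in the aged and the WT mice. In aged mice 5870 of 13596 genes were called, 2525 higher and 3345 lower in DP, and in WT mice 8622 of 13490, 4080 higher and 4542 lower. The largest differences in aged mice were Cd4 (log2 8.01), Cd8a (7.68) and Slc6a19 (7.11), higher in DP, and the mast cell protease gene Cpa3 (-9.69), Fat3 (-9.6) and Klrb1b (-8.41), lower. Fat3 stood at 123 CPM in aged DN 1 and at no more than 8.5 CPM in any other aged DN library. In WT mice they were Cd4 (7.33), Slc6a19 (6.36) and Cd8a (6.09), higher, and Mmp8 (at least about 240-fold lower), Il1r1 (at least about 179-fold lower) and Cacna1i (-9.2), lower. Cacna1i stood at 51.8 CPM in WT DN 2 and at no more than 6.03 CPM in any other WT DN library. DP stage genes were higher in aged (15 of 19, median 2.42, camera adjusted p = 9.63e-10) and WT mice (17 of 19, 2.41, adjusted p = 4.88e-09, and 0.0834 with an estimated correlation). Of the lists called, 15 in aged mice and 19 in WT mice, 0 and 2 held with an estimated correlation, the latter DN stage and gamma delta genes (0.0119 for both). Ferroptosis suppressors were lower in WT DP (3 of 26 higher, 14 lower, median -0.65, adjusted p = 0.0271, and 0.413 with an estimated correlation), a call that ended without WT DN 2 and WT DP 2 (0.0541).

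The WT groups, which carry a floxed allele and Cd4Cre, were also compared with the wild-type young groups of the same age. In DP cells 77 of 13083 genes were called, 30 higher and 47 lower in WT; the count was 31 without WT DP 1, 23 without WT DP 3, 37 without young DP 2, 27 without young DP 3, 25 without young DP 4 and 33 without young DP 5. Cttn (log2 1.54), Acpp (1.44) and Aldh1l1 (1.41) were the largest rises, and Igf2bp3 (-2.72), Cdc42bpa (-1.68) and Hspg2 (-1.61, adjusted p = 0.0189, and 0.0754 without WT DP 3) the largest falls. Lists called were B cell (median 0.31, camera adjusted p = 0.00997, and 0.405 with an estimated correlation), dendritic cell (0.64, adjusted p = 0.00997, and 0.405 with an estimated correlation) and oxidative phosphorylation genes (0.11, adjusted p = 0.0339, and 0.871 with an estimated correlation), higher, and m6A erasers and readers (adjusted p = 0.00997, and 0.31 with an estimated correlation), m6A writers (adjusted p = 0.0266, and 0.318 with an estimated correlation, 3 lower adjusted over the list alone) and the Wnt and Tcf list (adjusted p = 0.0266, and 0.7 with an estimated correlation), lower. In DN cells 3439 of 13702 genes were called, 1943 higher and 1496 lower (2259 without young DN 4 and 2102 without young DN 5). Of the 408 that changed at least 2-fold, 83 were higher and 325 lower, and of the 4201 called by DESeq2, 2053 were higher and 2148 lower. Kcnj8 (2.64), Styk1 (1.9) and Cttn (1.86) rose most, and Igf2bp3 (-3.48), Tmc5 (-2.47) and Plag1 (-2.4) fell most. Oxidative phosphorylation (35 of 37 higher, median 0.49, camera adjusted p = 3.68e-16) and ribosomal protein genes (36 of 47, 0.57, 6.46e-14) were higher, each at 0.567 with an estimated correlation, as were NK and innate lymphoid genes (8 of 11, 0.67, adjusted p = 0.000418, and 0.567 with an estimated correlation).

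Whether age acted differently on DP and DN cells was tested as an interaction over 14722 genes. A single gene was called, A630023P12Rik (log2 -4.91, adjusted p = 1.32e-05), an uncharacterised transcript at 11.4 ± 1.7 CPM in young DP, 0.859 ± 0.459 in aged DP, 2.06 ± 0.398 in young DN and 4.72 ± 2.12 in aged DN. It was at 2.38 CPM in WT DP and 2.59 CPM in KO DP, both of 10 weeks. With a replicate block, which the pairing of the aged libraries bears on, 10 genes were called. The fit over all 35 libraries gave 21, and 109 were called without the libraries that stand apart. DESeq2 called 85 genes, 23 of them higher, and 2229 had an unadjusted p under 0.05 by edgeR. Without aged DN 1 the count was 7, without young DN 3 it was 3, and without aged DN 2, young DN 2 or young DN 4 it was 2. Of the lists, 12 were called and 0 held with an estimated correlation.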

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

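The test of a lower share of DP cells and the interval beside each share of accounted genes were chosen after the result was seen; the other tests here were planned first.

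In 265 groups of 5 values (library quality, the ferroptosis and stage genes, and the means of marker lists), 42 values had a gap to the next library that was large against the range of their group. About 13 groups would show such a gap by chance, and values of the same library move together. Most belong to libraries high in marker genes of another cell type. In aged DN 5, the gap took 0.956 of the range for B cell markers (1090 CPM, next 95.7), 0.971 for dendritic cell markers (1140, next 91.5), 0.826 for endothelial markers and 0.88 for the share of the 10 leading genes (3.86%, next 2.76%). In WT DN 2 it took 0.914 for B cell (410, next 64.1), 0.956 for dendritic cell (584, next 53.2) and 0.85 for selection and single positive genes. Its Fth1 (0.863; 892 CPM, next 577), Gpx4 (0.778; 116, next 84.5), Slc3a2 (0.725) and leading-gene share (0.785) were high, and its Rag1 (0.767; 306, next 784), Il2ra (0.731; 307, next 529) and Tfrc (0.777; 191, next 347) low. Aged DP 5 was high in B cell (0.831; 139, next 57.3), dendritic cell (0.898; 71.7, next 19.6), macrophage (0.794), NK (0.756) and selection and single positive genes (0.773).

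Aged DN 1 was the highest of its group in gamma delta and innate-like T cell genes (0.957; 593 CPM, next 84.2), Aifm2 (0.864; 6.62, next 1.61), Hmox1 (0.775; 5.34, next 1.33), fibroblast genes (0.77) and Slc3a2 (0.724). KO DP 2 was high in Gpx4 (0.752; 182 CPM, next 94.8) and Fth1 (0.826; 447, next 316) and low in Slc3a2 (0.74; 43.6, next 72.9) and Rag2 (0.736; 201, next 250). Young DN 3 was high in Hmox1 (0.946; 8.83, next 1.33), granulocyte (0.767; 115, next 48.8), fibroblast (0.824) and macrophage genes (0.739). Young DN 5 was high in Cd4 (0.895; 107, next 16.7), Cd8a (0.902; 159, next 29.3) and Cd8b1 (0.781; 123, next 52.3), the genes of DP cells. WT DP 4 was high in Fth1 (0.733) and granulocyte genes (0.815; 0.892, next 0.314). Young DP 1 was high in gamma delta genes (0.741), and young DP 2 low in Kit (0.857; 4.23, next 6.75) and DN stage genes (0.737). Ptgs2 was high in WT DN 4 (0.748) and in young DP 3 (1), where it was the only library of its group with a count.

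The difference between aged and young libraries was not the same in DP and DN cells for A630023P12Rik (log2 difference -4.91, edgeR adjusted p = 1.32e-05). That gene was at 11.4 CPM in young DP but 2.38 CPM in WT DP and 2.59 CPM in KO DP of the same age, so age is not shown to be what lowered it. The same test called 12 lists with the preset correlation and 0 with an estimated one (adjusted p = 0.372 for granulocyte genes and 0.633 for the others). Medians of the difference (DP change minus DN change) were positive for S phase (0.66; camera adjusted p = 1.45e-10), G2/M (0.72; 2.21e-10), granulocyte (2.06; 6.6e-09), oxidative phosphorylation (0.24; 2.51e-05), ribosome biogenesis (0.31; 9.82e-05), DP stage (0.54; 0.00195), ribosomal protein (0.15; 0.00242), RNA processing (0.24; 0.00677), V(D)J recombination (0.32; 0.0145) and cholesterol synthesis genes (0.29; 0.0215). They were negative for p53 targets (-0.41; 0.0236) and selection and single positive genes (-0.91; 0.0236). Without the libraries that stand apart, the calls on DP stage (0.785), ribosome biogenesis (0.405), cholesterol synthesis (0.16), oxidative phosphorylation (0.14), V(D)J recombination (0.14) and RNA processing genes (0.0887) ended.

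Genes raised in KO DP include many of other blood cells, such as Cd22, Cd74 and S100a9, and RNA of B cells, which a sort on CD4 and CD8 should keep out of DP samples, is a candidate explanation for part of them. The increase of the called B cell list members was set against that predicted from how they vary with one another over the DN libraries. The median of observed over predicted was 0.651, within the bounds of 0.5 to 2 set beforehand, and 0.843 with slopes from WT DN alone. The prediction itself uses the rise of the other list members in KO DP. A median within the bounds is thus likely whenever the list rises together. This test therefore does not tell B cell RNA from a change within DP cells. Of the 15 members, 13 lay within these bounds. The slopes predicted more than was seen for most members, up to 247% of the rise of Pax5, but only 25.2% of that of Igkc. Of the other 181 raised genes, the same slopes account for 33.1% (60 genes, exact Clopper-Pearson 95% interval 26.3 to 40.5, and 28.7% with slopes from WT DN alone). The interval treats genes that vary together as independent, so it is likely too narrow. In these libraries, B cell RNA as the slopes measure it thus does not account for most of the 181 genes. The slopes rest mainly on aged DN 5 and WT DN 2, with B cell markers at 1090 and 410 CPM, and those from WT DN alone on WT DN 2. A lower share of DP cells would raise other cell types alike; list medians differed by 2.08, from 1.41 for macrophage to 3.49 for B cell genes (spread of members 1.95), but macrophage genes averaged 14.6 CPM in WT DP and 18 in WT DN, a baseline that would hide a small added share, so this test decides nothing. That lower share, a response to the loss of Mettl3, other cells in the sort gate, and doublets stay open; the deletion could not be checked on gene-level counts, and Rag1 and Gpx4 move with the same library, KO DP 2, in which the fewest genes of its group had a count (12306).

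Genes raised both in KO DP and in aged DP may also come from B cells in the samples. The DN slopes predict at least 50% of the rise for 51.9% of the 27 genes in both comparisons (14 genes, 95% interval 31.9 to 71.3, and 55.6% with slopes from WT DN alone). That interval holds the bound of the test, and it is likely too narrow, since it too treats genes as independent. B cell RNA and a change within DP cells thus cannot be told apart for these genes as a set. Cd22, Ms4a1, Cd74, H2-Aa, H2-Ab1 and H2-Eb1 reach that bound, but in aged DP the slopes predict far more than was seen, from 222% of the rise of H2-Ab1 to 303% of that of Cd22, so the prediction misses them there; the immunoglobulin genes Igkc, Ighg2b and Ighg2c, and Irf1 and Il12rb1, rose beyond what the slopes predict. Genes that DN cells express themselves, such as Blk, have slopes that do not measure B cells, and the slopes may include other cells that vary with B cells. More B cells in the aged and knockout thymus, and a looser sort of these samples, were not tested apart.

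WT DN and young DN libraries, both from 10-week mice, differed in 3439 genes, ribosomal protein and oxidative phosphorylation genes higher in WT. Depth differed between these groups, but thinning the WT DN counts to the young DN depth left 3427 genes, which argues against depth as the cause. Removing a trend on gene length in each library left 3083 (rho -0.36 between the change and gene length, across genes), which argues against length alone. Malat1, a nuclear RNA, was at 311 CPM in WT DN, 988 in young DN and 2060 in WT DP, and fewer genes had a count in WT DN (17000 ± 778) than in young DN (19400 ± 261, exact permutation p = 0.00794, adjusted p = 0.0289) despite the greater depth. Xist ran from 3380 to 4220 CPM in young DN and was at 2450 and 822 CPM in WT DN 1 and WT DN 2. It was at 0.787, 0.239 and 0 CPM in WT DN 3, WT DN 4 and WT DN 5, so the mix of sexes may differ too. The Xist level was not used as a covariate here. Sex, a library batch, RNA quality, a difference of strain or litter, and the floxed allele with Cd4Cre stay open and untested. No label names a batch.

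Other splits of the same libraries were fitted to ask whether the counts could arise by chance, with 100 splits for each comparison, the real split included. No other split called as many genes for KO DP against WT DP (211 genes, highest other split 1), aged against young DP (123, highest other 5), aged against young DN (37, highest other 0), the 3 stage comparisons (9697, 5870 and 8622, highest other 0 in each), and WT DN against young DN (3439, highest other 1). A share of 1 in 100 is the smallest that these splits allow, which argues against chance but does not exclude it. Other splits of the stage comparisons mix DN and DP cells on each side. That widens the spread, so a count of 0 there says little. For WT DP against young DP and for the interaction 2 of the 100 splits, the real one included, gave as many genes. Another split thus matched the 1 gene of the interaction, and a count of 1 does not argue against chance. For WT DP against young DP, with 77 genes, the other split called 638 genes. It set WT DP 1, WT DP 2, young DP 3, young DP 4 and young DP 5 against the rest, which points to a structure of the samples. Xist ran from 2410 to 3200 CPM in those libraries. Among the rest it ran from 0.205 to 0.754 CPM in the WT DP libraries and was at 2110 and 3250 CPM in young DP 1 and young DP 2. The split thus follows Xist within WT DP but not within young DP, and the real groups differ in Xist too. Whether sex lies behind either count was not tested.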

How the results depend on the processing

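Leaving out the libraries that stand apart and adding Xist as a covariate were alternatives chosen after the result was seen; the others were planned first.

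For 28 results (counts of genes, of lists, the shared count and the ferroptosis lists), 141 values were computed under alternatives other than leaving out 1 library. Of these, 94 kept their side of the threshold or stayed within 1.5 times, 47 did not and 0 reversed. A reversal was scored only for the ferroptosis lists, since the other results are counts without a direction. The balance of higher and lower genes did turn in places. For WT DN against young DN it went from 1943 of 3439 higher to 83 of 408 higher at a 2-fold minimum. Of 412 results on named genes, 6675 values were computed; 6150 were the same, 400 lost the call, 125 gained it and 0 reversed.

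DESeq2 called more genes: 606 for KO DP against WT DP (210 shared with edgeR's), 329 for aged DP, 924 for aged DN (700 higher, against 22 of 37), 410 for WT DP against young DP, 85 for the interaction (23 higher) and 76 shared between KO and age. Without a filter on low counts, 353 genes were called for aged DP and 149 for WT DP against young DP. The fit over all 35 libraries, which pools the spread of all groups, called 181 for KO DP (34 lower, 83 shared), 26 for aged DP, 2193 for aged DN (34 shared), 3 for WT DP against young DP, 1663 for WT DN against young DN and 21 for the interaction. A replicate block, which pairs libraries by number, gave 61 for KO DP, 1 for aged DN, 8 for WT DP against young DP, 10 for the interaction and 15 shared genes. Only between aged DN and aged DP did all 5 pairs match best by number. In the young stages 3 pairs did (r from 0.02 to 0.14), and in the WT stages 3 (r from -0.13 to 0.2). Xist in the WT stages was at 822 CPM or more in both libraries of numbers 1 and 2. It was under 1 CPM in those of numbers 3, 4 and 5, so pairing there is not excluded. For KO DP against WT DP 1 pair matched best by number, and r ran from -0.24 to 0.17. Without the libraries that stand apart, 534 genes were called for KO DP (211 shared), 706 for aged DN (37 shared) and 109 for the interaction. A 2-fold minimum, which can only remove genes, left 65 for aged DP, 3923, 3223 and 4267 for the young, aged and WT stage comparisons, 26 for WT DP against young DP and 408 (83 higher) for WT DN against young DN. RLE factors changed no count by over 1.5 times, and Xist as a covariate gave 157 genes for KO DP. The cause of the other differences was not tested.

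List calls with the preset correlation numbered 17 for KO DP, 18 for aged DP, 15 for aged DN, 18, 15 and 19 for the young, aged and WT stage comparisons, 6 and 9 for WT against young DP and DN, and 12 for the interaction. An estimated correlation, which allows for genes that vary together, left 0, 0, 0, 1, 0, 2, 0, 0 and 0. Such variation does not explain every lost call. That on m6A writers in KO DP ended (camera adjusted p from 0.012 to 0.0832) with an estimate of -0.085, under the preset 0.01. Fry, which asks another question, called 15, 2, 4, 35, 30, 32, 2, 16 and 1. The ferroptosis drivers in aged DP had an adjusted p = 0.315 with an estimated correlation, 0.0652 by fry and 0.0598 without the libraries that stand apart.

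Leaving out each library in turn gave ranges of 101 to 534 genes for KO DP, 58 to 136 for aged DP, 10 to 185 for aged DN, 9350 to 9817 for the young, 4855 to 6589 for the aged and 8234 to 9203 for the WT stages, 23 to 98 for WT DP against young DP, 2102 to 4392 for WT DN against young DN, 1 to 7 for the interaction and 9 to 41 for the shared genes. Adjusted p-values of suppressors, drivers and iron handling genes ranged from 0.382 to 0.995, 0.589 to 0.992 and 0.435 to 0.944 for KO DP, from 0.0861 to 0.517, 0.015 to 0.0614 and 0.11 to 0.517 for aged DP, and from 0.35 to 0.694, 0.347 to 0.874 and 0.261 to 0.461 for aged DN.

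Of called named genes, 10 of 43 kept their call in every alternative for KO DP, among them Serpina3g, Igkc, H2-K1, Gzmb, Cybb and Irf7; 8 of 30 did for aged DP, among them Bmpr1a, Igf2bp3, Cdc42bpa, Igkc and Jchain; 1 of 20 for aged DN, Igf2bp3; and 140 of 150 for young DP against DN. Recovery in simulated counts at 2-fold, lowest for aged against young DN at 34%, limits what that comparison could call.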

Other observations

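All comparisons of gene levels in this part were chosen after the result was seen, and none was tested beyond the comparisons already given.

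The RNA-binding protein gene Igf2bp3, which belongs to the genes of fetal blood formation, was high in both young wild-type groups and low in all the others. It stood at 30.8 ± 1.59 CPM in young DN and 26.8 ± 2.34 in young DP, against 3.1 ± 0.289 in aged DN, 4.36 ± 1.82 in aged DP, 2.78 ± 0.68 in WT DN, 4.03 ± 0.782 in WT DP and 3.27 ± 1.54 in KO DP. The last 3 groups are 10 weeks old like the young groups. The kinase gene Cdc42bpa was arranged the same way, at 21.5 and 19.1 CPM in young DN and DP and from 2.48 CPM in KO DP to 6.64 CPM in aged DN elsewhere. The actin regulator gene Cttn had the opposite arrangement in DP cells, at 4.18 CPM in young, 12.2 in aged, 12.2 in WT and 10.2 in KO. Kcnj8 did so in DN cells, at 0.843 CPM in young, 5.35 in aged and 5.27 in WT. Age alone does not order these genes. The comparisons of aged and of WT with young share the young libraries, so a call in both is not independent evidence.

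Bmpr1a, by contrast, was high in the aged groups alone, at 17.1 CPM in aged DN and 16 CPM in aged DP. It was at 0.754 and 0.471 CPM in young DN and DP, 1.19 and 0.405 CPM in WT DN and DP, and 0.717 CPM in KO DP. A630023P12Rik was highest in young DP, at 11.4 CPM (9.21 to 13.8), followed by aged DN at 4.72 ± 2.12 CPM (up to 8.47), and was at 2.38 CPM in WT DP, 2.59 in KO DP and 2.51 in WT DN. Granulocyte markers averaged 51.4 CPM in young DN, 28 in WT DN and 8.49 in aged DN, and 3.24 CPM in KO DP against 0.377 in WT DP.

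Xist was at 2530 CPM in WT DP 1 and 2410 CPM in WT DP 2 and at 2400, 907 and 649 CPM in KO DP 1, KO DP 2 and KO DP 4, and near 0 in the other libraries of these groups. WT DN 1 stood at 2450 CPM and WT DN 2 at 822 CPM. Intermediate levels were thus seen in 3 libraries.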
